A study of Mus musculus with 13 samples.

How the data were processed

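RNA of 13 flow-sorted samples of mouse CD8 T cells was hybridised to Illumina MouseRef-8 v2.0 bead arrays, 1 array per sample. Groups were taken from the sample titles. They are naive (n = 3), effector (n = 3), early lesion (days 8 to 12, n = 3) and late lesion cells (days 32 to 34, n = 4). Per the labels' protocols, sorted cells were frozen until all samples had been collected, RNA of high integrity was amplified with the Ovation PicoSL system, and biotin was added with the Encore BiotinIL module. A separate label field names the Illumina TotalPrep kit instead, and which kit was used is not settled here.

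The deposited table of signals holds intensity values, 1 mean bead signal per probe and array. Judged from these values, it was neither background-subtracted nor normalized between arrays. The scanner software and its background setting are not given in the sources used here. Beside each signal the deposited table gives a detection p-value, per the file headers. The authors also deposited log2 values of the same arrays, and the submitters' processing notes name lumi 2.14.1. Set against the scanner signals, each deposited log2 column kept the rank order of its array (Spearman correlation of 1 on each array) and all columns had a median of 7.33. The deposited values were read as quantile-normalized without background subtraction. Kept ranks and equal medians do not settle this, since median scaling or subtraction of a constant would also give them. The base of the logarithm was taken from the scale of the signals, and no step of the deposited processing is stated. No column of per-sample values was left unused.

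Gene names came from the platform annotation supplied with the data. Of 25697 probes, 23978 had 1 gene symbol, 0 had several and 1719 had none, and 23962 symbols were updated through their gene identifiers. The named probes covered 16593 genes. Genes without a probe here, Tox, Tcf7 and Mki67 among those meant to be named, were not analysed here. No coordinates are given, since the sources used here name no genome build.

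Signals were corrected and normalized with the neqc function of limma 3.58.1 in R 4.3.3. It fits a normal and exponential background model from the detection p-values, adds an offset of 16, normalizes by quantiles and takes log2. Probes with a detection p-value below 0.05 on at least 3 arrays were kept, which left 10653. For each gene the probe with the highest mean over all 13 arrays was used, and unnamed probes stayed as they were. This gave 7988 features, 7310 named and 678 unnamed. Genes whose probes disagreed were few. Of 350 genes with several called probes in the comparison of early lesion with naive cells, 3 had probes called in opposite directions, and in the other comparisons the number was 0 to 4. Detected probes made up 27.1% to 42.3% per array, and the brightest array had a median signal 1.48 times that of the dimmest.

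A linear model with 1 mean per group was fitted to all 13 arrays with lmFit and eBayes of limma, which left 9 residual and 4.46 prior degrees of freedom. Each of 6 comparisons was a contrast of this model. Tests were two-sided, and a feature was called changed at a Benjamini-Hochberg adjusted p below 0.05. Every adjusted p for a gene in the text is from this limma model. For a gene undetected on every array of the dimmer group, the fold is a lower bound. It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest detected signal and the gene's own signal, while its adjusted p is that of the model.

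The 26 gene lists were written from general knowledge before the data were examined, as were the model, the thresholds, the rule for named genes and most alternatives. They cover inhibitory receptors, transcription factors of chronically stimulated T cells, naive and memory T cell genes, cytotoxic and terminal effector genes, effector cytokines, cytokine receptors and signal transducers, costimulation, negative regulators of TCR signalling, chemokines and their receptors, tissue residency, integrins and adhesion, S phase, G2 and M phase, glycolysis, oxidative phosphorylation, interferon-stimulated genes, apoptosis regulators, and immediate early and dissociation stress genes. Lists of T cell identity, hepatocyte, myeloid, B cell, NK cell, CD4 and regulatory T cell, liver endothelial and stellate, and erythroid and platelet genes served to look for other cells in the sorts. Some genes stand on more than 1 list, such as Klrg1, Ccr7, Bcl2 and Cd2. Each list with at least 2 tested members was tested with fry, adjusted over all lists and comparisons, and with camera with an estimated correlation as the alternative. None of the 93 list calls made with fry held with the estimated correlation. Camera asks whether a list changes more than other genes, whereas fry asks whether its members change. A call lost with camera is therefore not due to correlation alone.

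Named genes followed 1 rule. In each of the first 4 comparisons it took the 10 largest increases and 10 largest decreases (5 and 5 in the last 2) among called single-symbol genes whose arrays did not overlap and that were detected on every array of the higher group and at least 1 of the lower. It added in each direction up to 5 (or 2) genes with the largest lower bound, up to 4 members per list with the smallest p among those called, or the 2 with the largest difference where none was, and 17 T cell and liver genes set whatever their result. The text describes part of the genes this rule names.

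Overlaps of calls between comparisons that share control arrays were set beside 100 simulated pairs of unchanged groups, made by permuting residual arrays with random signs, and beside the overlap of independent lists. The code was tested on simulated data with 200 genes changed, drawn as normal noise around each gene's mean with the spread the model gave that gene. At a planted 2-fold change, 37.3% of genes were recovered for effector against naive cells, 44.8% for early lesion against naive, 53.7% for early lesion against effector, 62.7% for late against early lesion, 61.2% for late lesion against naive and 65.7% for late lesion against effector cells. At 4-fold, 93.9% to 98.5% were recovered, and at 1.5-fold 2.99% to 11.9%, so a gene with a small change and no call is not shown to be unchanged. Of 100 unchanged lists, fry put 3 under an unadjusted p of 0.05.

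Alternatives tried were no background correction, median scaling, cyclic loess, an offset of 50, the authors' deposited values, no filter and a stricter filter, all probes, a fit of only the groups compared, eBayes with trend and robust estimation, array weights, a replicate block, a 2-fold threshold, camera for lists, and leaving out each array in turn. A slide block was meant to be tried but was not run, since the files show no slide. Other alternatives were added after the data were seen. These used the difference of Xist and Eif2s3y, the mean of Cd79a and Cd79b, or the median signal as a covariate, or left out effector replicate 1 and late lesion replicate 1. Where leaving out 1 array removed the probe of a called gene named in the report, the fit was repeated with the probes held as with all arrays. Probes that failed the filter entered no gene test and are shown only as marker levels.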

Results

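Transcript levels were measured in 13 samples of flow-sorted mouse CD8 T cells, 1 single-colour bead array each. All cells carried a transgenic T cell receptor (TCR) for an epitope, numbered I, of the viral oncoprotein SV40 large T. Naive cells (n = 3) were sorted from spleen as CD8-positive, CD44-low cells. Effector cells (n = 3) were donor cells recovered from spleens of B6 mice about 1 week after infection with Listeria bacteria carrying the epitope. Lesion cells were donor cells recovered from pre-malignant livers of mice in which tamoxifen had switched on the oncogene. Early lesion cells (n = 3) were taken at days 8, 12 and 9 after tamoxifen (replicates 1, 2 and 3). Late lesion cells (n = 4) were taken at day 32, day 33 and, for replicates 3 and 4, day 34. The design asks how tumour-specific CD8 T cells at an early and a later stage of lesion growth differ from naive cells and from effector cells of an acute infection. Spleen and liver separate the naive and effector groups from the lesion groups, so tissue and antigen setting cannot be told apart there. The source label reads mouse splenocytes for every sample, although the protocol of the lesion samples names liver.

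Between 27.1% and 42.3% of the 25697 probes were detected per array (detection p-value below 0.05), and median scanner signals ran from 123.4 to 183.2. The day 8 array had the lowest of both. Replicates correlated across genes at 0.959 to 0.979 in the naive, 0.937 to 0.965 in the effector, 0.872 to 0.929 in the early lesion and 0.931 to 0.965 in the late lesion group, and none held identical values. After filtering, 7988 features were tested, 7310 of them named genes. Levels are normalized log2 signals as mean ± SD, with n = 3 for naive, effector and early lesion and n = 4 for late lesion arrays, and differences are log2 values ± SE. A fold against a group with no array above background is a lower bound ("at least"). For each gene called changed below, the arrays of the groups compared do not overlap, except where stated. A list's median is that of its members' log2 differences, and its fry test asks whether the members move 1 way on balance, not whether they differ from other genes. The adjusted p with an estimated correlation is that of camera, which does ask whether they differ from other genes. Beside a call that ended under an alternative setting, the range is that of its adjusted p over all alternatives besides the estimated correlation. The number of arrays limits the precision. Because the labels do not say that replicates were separate mice, p-values measure only the spread between these samples.

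**Figure D1:**
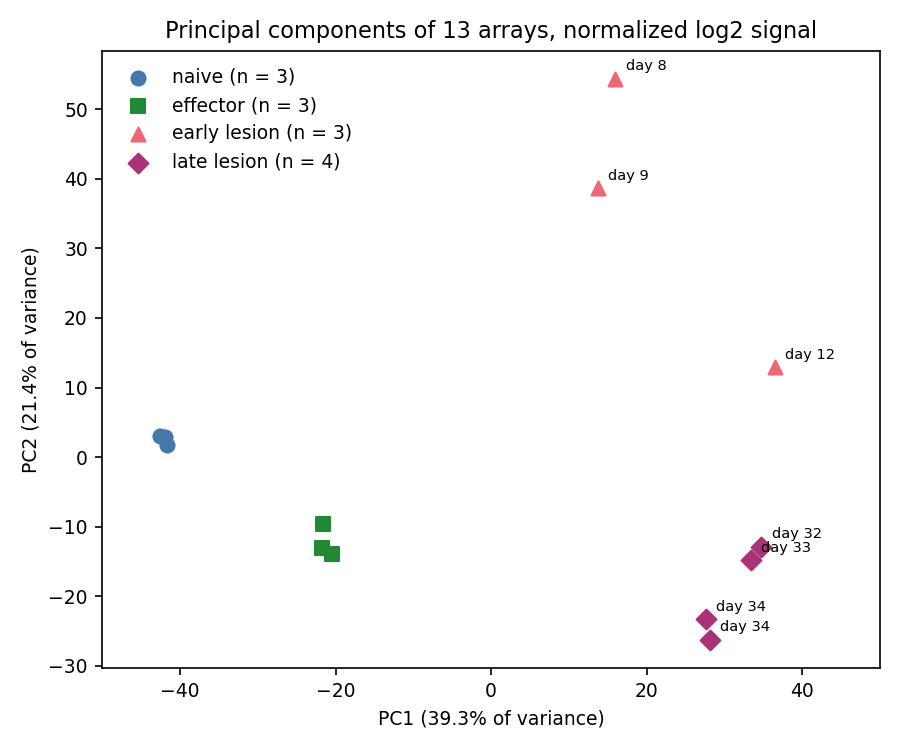
Each point is 1 array placed by its scores on principal component 1 (39.3% of variance) and component 2 (21.4%) of the normalized log2 signals, with lesion arrays marked by day after tamoxifen. Naive and effector arrays lie between -42.6 and -20.4 on component 1 and lesion arrays between 13.7 and 36.5, and on component 2 the day 12 array (12.9) lies between the other early arrays (38.6 and 54.4) and the late arrays (-26.2 to -12.8).

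**Figure D2:**
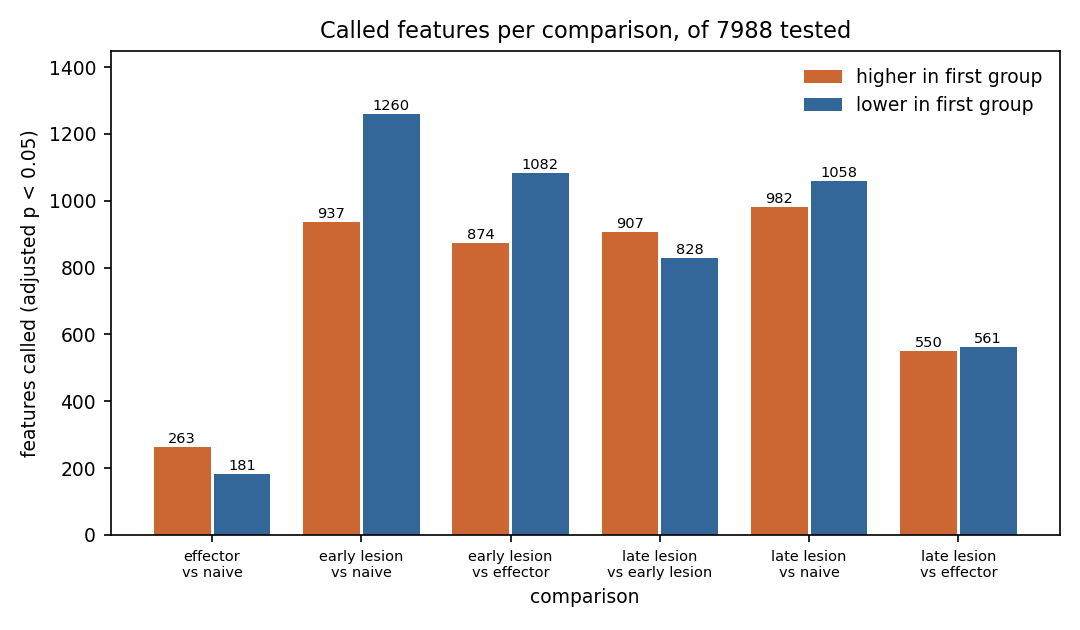
Bars give the number of features called higher or lower (adjusted p below 0.05) in the first-named group of each comparison, out of 7988 tested. The counts run from 181 to 1260.

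Effector cells were compared with naive cells to show the response to infection in the spleen. T-bet and part of the cytotoxic and adhesion genes rose, and part of the naive and memory genes fell. Cd44, whose protein was kept low by the gate for naive cells, was 11.8-fold higher (9.13 ± 0.07 against 5.58 ± 0.18, difference 3.56 ± 0.16, adjusted p = 3.52e-08). Granzyme A (Gzma) rose 25.2-fold (adjusted p = 0.00317), the chemokine Ccl5 27.2-fold (adjusted p = 9.34e-05) and the effector transcription factor T-bet (Tbx21) at least 11.0-fold (adjusted p = 5.66e-05). Itgae, which encodes the integrin chain CD103, was lower by 24.6-fold (adjusted p = 4.50e-05). Of 7988 features, 444 were called, 263 higher and 181 lower, and 203 and 115 of these differed at least 2-fold.

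Of 19 cytotoxic and terminal effector genes, 10 rose and none fell (13 and 0 adjusted over the list alone; median 1.67, fry adjusted p = 9.42e-05, adjusted p = 0.120 with an estimated correlation). They included granzyme K (Gzmk, at least 14.9-fold, adjusted p = 0.00112), the regulator Zeb2 (at least 7.53-fold, adjusted p = 6.56e-06), the sphingosine phosphate receptor S1pr5 (5.60-fold, adjusted p = 3.68e-06) and Klrg1, a receptor of short-lived effector cells (at least 4.14-fold, adjusted p = 0.000129). Klrg1 was also the single call among 11 inhibitory receptors (2 and 0 adjusted over the list alone; median 0.33, fry adjusted p = 0.000260, adjusted p = 0.206 with an estimated correlation). Among 11 chemokines and their receptors, 4 rose and 2 fell (5 and 2 adjusted over the list alone; median 0.71, fry adjusted p = 6.91e-05, adjusted p = 0.152 with an estimated correlation). Ccl4 (at least 9.52-fold) and Cxcr3 (at least 12.3-fold) were higher, and the gut-homing receptor Ccr9 was at least 7.28-fold (adjusted p = 3.52e-08) lower. Integrin and adhesion genes rose in 5 of 10 cases (5 and 0 adjusted over the list alone; median 0.41, fry adjusted p = 3.48e-06, adjusted p = 0.120 with an estimated correlation), among them Itgb1 (6.78-fold) and Itga4 (2.99-fold). Further increases were measured for the protease inhibitor Ctla2a (27.1-fold, adjusted p = 5.18e-07), the calcium-binding S100a6 (19.3-fold), pleckstrin (Plek, 18.1-fold), the IL-18 receptor subunit Il18rap (at least 7.50-fold), the transcription factor Bhlhe40 (at least 3.07-fold), the G protein regulator Rgs1 (7.50-fold) and hexokinase Hk2 (4.89-fold). Lists of chronic stimulation factors, TCR regulators, cytokine receptors, effector cytokines and glycolysis genes were also called with fry. Their medians were positive in each alternative. The calls ended in 4, 1, 1, 10 and 2 of 29 alternatives, in that order, besides the estimated correlation.

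Naive and memory genes fell in 8 of 17 cases and none rose (0 and 10 adjusted over the list alone; median -1.15, fry adjusted p = 0.00153, adjusted p = 0.168 with an estimated correlation). Lower members included the actin cross-linker Actn1 (3.05-fold, adjusted p = 0.000442), both IL-6 receptor chains (Il6ra, at least 1.79-fold, and Il6st, 3.80-fold) and Igfbp4 (at least 7.26-fold). The cytokine signalling inhibitor Socs3 (8.23-fold, adjusted p = 6.40e-05), AMP deaminase Ampd1 (at least 6.89-fold) and the cell cycle regulator Rgcc (9.44-fold) fell as well. Oasl2, 4.56-fold lower, was the single call among 18 interferon-stimulated genes (median -0.29, fry adjusted p = 0.0507). The IL-7 receptor gene Il7r stood at 11.01 ± 0.23 against 10.56 ± 0.05 (adjusted p = 0.646).

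Of 17 S phase genes, Rrm2 alone was higher, and of 14 G2 and M phase genes none (fry adjusted p = 0.971 and 0.786). The S phase median was -0.07 and its mean 0.01. No member was called among 9 costimulation, 22 oxidative phosphorylation and 10 T cell identity genes (medians 0.28, -0.09 and -0.07, fry adjusted p = 0.857, 0.416 and 0.318). Bcl2a1d was higher and Bcl2 lower among 11 apoptosis regulators (median 0.18, fry adjusted p = 0.341). Ier3 was higher and Egr1 and Dusp1 lower among 12 immediate early and dissociation stress genes (median -0.07, fry adjusted p = 0.278).

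Markers listed for other cell types rose in the effector group, but the cells that hold these transcripts were not identified. Of 9 B cell markers, 7 rose (8 and 0 adjusted over the list alone; median 2.65, fry adjusted p = 0.00378, adjusted p = 0.168 with an estimated correlation). They included the MHC class II chain H2-Ab1 (19.3-fold, adjusted p = 0.00293) and the invariant chain Cd74 (13.1-fold, adjusted p = 0.00323). Of 8 myeloid markers, 3 rose (4 and 0 adjusted over the list alone; median 1.30, fry adjusted p = 0.000342, adjusted p = 0.168 with an estimated correlation). These were Cd163 (5.24-fold), Adgre1 (at least 2.31-fold) and Itgax, which encodes CD11c (at least 9.31-fold, adjusted p = 3.52e-08). Itgax stood at 8.85, 9.04 and 9.43 on effector replicates 1 to 3, the reverse of the order of the B cell markers. Its source and that of Nrp1 below were not tested. Nrp1, 1 of 2 CD4 and regulatory T cell markers tested, rose at least 3.09-fold (adjusted p = 0.00109), in a list with median 1.35, fry adjusted p = 0.00252, adjusted p = 0.206 with an estimated correlation. The 2 hepatocyte, 2 erythroid or platelet and 4 NK cell markers tested gave no call (medians 0.70, 0.32 and 0.14, fry adjusted p = 0.212, 0.569 and 0.607). Only 1 liver endothelial marker passed the filter, so that list was not tested. Without effector replicate 1 or 3 the difference of Cd74 was 2.97 or 4.32, and without replicate 1 that of H2-Ab1 was 3.63 in place of 4.27. With the mean level of Cd79a and Cd79b as a covariate, chosen after seeing the data, the calls of Gzma, Gzmk, Il6st, Actn1, Hk2, H2-Ab1, Cd74, Cd163 and Adgre1 ended (adjusted p from 0.0515 to 0.705). Of 339 calls that it ended, 220 kept at least 80% of their difference, 52 kept less than 50%, and the median standard error was 1.69 times as large. Gzma went from 4.66 ± 0.81 to 4.97 ± 1.40 (log2, SE) and Actn1 from -1.61 ± 0.22 to -1.66 ± 0.37, which lost precision, whereas Cd74 went from 3.71 ± 0.65 to 1.36 ± 0.75 and Cd163 from 2.39 ± 0.27 to 1.49 ± 0.34. The call of the B cell list ended too (adjusted p = 0.362, range 0.000296 to 0.362).

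The count of 444 moved with single arrays. It was 210, 250 and 203 without naive replicates 1, 2 and 3, 286 and 220 without effector replicates 1 and 2, and 282 without effector replicate 1 and late lesion replicate 1 together. Median scaling gave 256 calls, a sex-linked covariate (Xist minus Eif2s3y) 263, the Cd79a and Cd79b covariate 115 and array weights 1698. Xist minus Eif2s3y was 4.07 to 5.69 on all effector arrays, naive replicate 3, early lesion replicates 1 and 2 and late lesion replicates 3 and 4. It was -4.03 to -3.50 on naive replicates 1 and 2, early lesion replicate 3 and late lesion replicates 1 and 2, so each comparison with effector cells is partly confounded with this difference. That covariate ended 294 of 1956 calls for early lesion and 228 of 1111 for late lesion against effector cells. Of these, 293 and 204 kept at least 80% of their difference. The naive and memory list was not called without naive replicate 1 or 3 (adjusted p = 0.0547 and 0.0588, range 2.26e-07 to 0.0588), nor the B cell list when only these groups were fitted (0.0612). Median scaling ended the calls of integrins (0.0581, range 9.91e-08 to 0.0581) and inhibitory receptors (0.0813, range 1.31e-05 to 0.0813), and the latter also ended without those 2 arrays (0.0698).

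**Figure D3:**
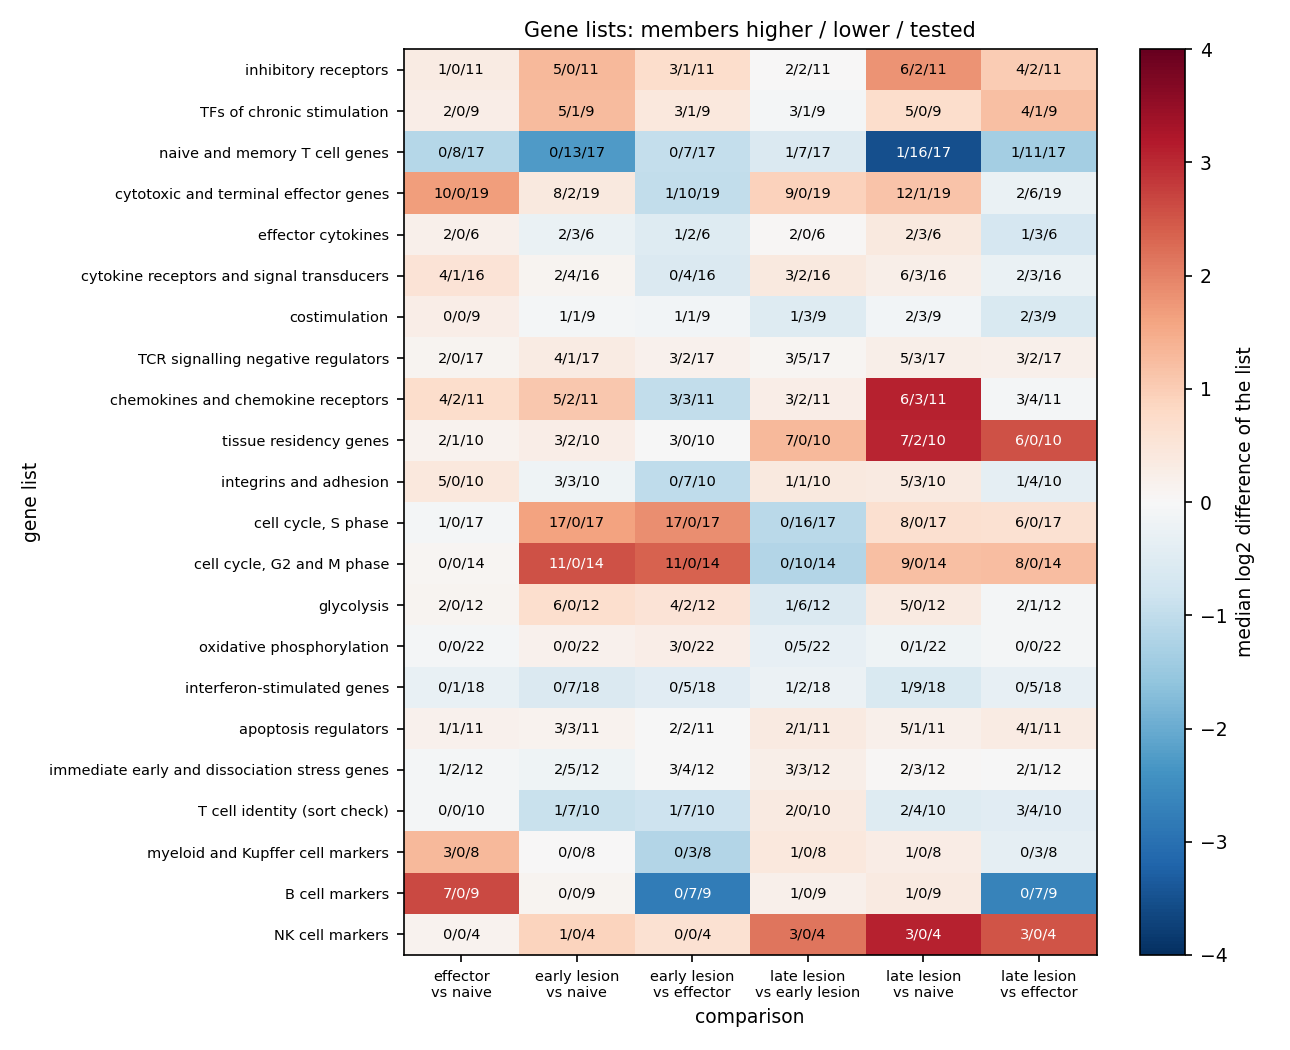
Rows are the gene lists with more than 2 tested members and columns are comparisons, with colour giving the median log2 difference of a list's members and text the members called higher, called lower and tested. S phase genes stand at 17 higher of 17 in early lesion cells against naive and against effector cells and at 16 lower of 17 in late against early lesion cells.

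Early lesion cells were compared with naive cells to describe tumour-specific cells in the liver within the first 12 days. S phase genes, most G2 and M phase genes and part of the glycolysis and inhibitory receptor genes rose, and most naive and memory genes fell. The linker histone H1f5 was 35.5-fold higher (10.85 ± 0.16 against 5.70 ± 0.13, adjusted p = 3.18e-07) and Ccl4 at least 44.6-fold (adjusted p = 2.23e-08), while Il7r was 16.7-fold lower (6.49 ± 1.14 against 10.56 ± 0.05, adjusted p = 1.37e-05). In all, 2197 features were called, 937 higher and 1260 lower, with 531 and 624 at least 2-fold.

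All 17 S phase genes rose (17 and 0 adjusted over the list alone; median 1.61, fry adjusted p = 1.38e-05, adjusted p = 0.120 with an estimated correlation), and so did 11 of 14 G2 and M phase genes (11 and 0 adjusted over the list alone; median 2.55, fry adjusted p = 0.000176, adjusted p = 0.168 with an estimated correlation). Examples are both subunits of ribonucleotide reductase, Rrm2 (15.2-fold, adjusted p = 5.97e-07) and Rrm1 (5.71-fold), the DNA methylation factor Uhrf1 (8.18-fold), topoisomerase Top2a (at least 8.15-fold) and the spindle kinesin Kif11 (12.3-fold). The related kinesin Kif15 rose at least 10.8-fold (adjusted p = 1.76e-06). Glycolysis genes rose in 6 of 12 cases and none fell (8 and 2 adjusted over the list alone; median 0.68, fry adjusted p = 2.07e-05, adjusted p = 0.120 with an estimated correlation). Hk2 was 9.94-fold, Tpi1 4.69-fold (adjusted p = 4.69e-06) and Gapdh 2.59-fold higher.

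Inhibitory receptors rose in 5 of 11 cases and none fell (5 and 0 adjusted over the list alone; median 1.29, fry adjusted p = 3.48e-06, adjusted p = 0.124 with an estimated correlation). Lag3 was higher by at least 3.19-fold (adjusted p = 5.62e-07), PD-1 (Pdcd1) by at least 2.22-fold (adjusted p = 0.00250), Ctla4 by at least 2.86-fold (adjusted p = 0.00305) and Cd160 by 3.09-fold (adjusted p = 0.00729). Of 9 transcription factors linked to chronic stimulation, 5 rose and 1 fell (5 and 1 adjusted over the list alone; median 1.25, fry adjusted p = 6.91e-05, adjusted p = 0.138 with an estimated correlation). The nuclear receptor Nr4a2 (9.25-fold, adjusted p = 3.69e-05), Helios (Ikzf2, 4.31-fold) and Bhlhe40 (at least 4.12-fold) were higher. Among 17 negative regulators of TCR signalling, 4 rose and 1 fell (5 and 2 adjusted over the list alone; median 0.32, fry adjusted p = 1.38e-05, adjusted p = 0.168 with an estimated correlation). Ubash3b (13.3-fold, adjusted p = 2.35e-08) and Spry2 (at least 5.91-fold, adjusted p = 1.30e-06) rose. Of 11 chemokine genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone; median 1.09, fry adjusted p = 4.85e-05, adjusted p = 0.206 with an estimated correlation). Ccl3 rose by at least 7.89-fold and Xcl1, which attracts cross-presenting dendritic cells, by 28.6-fold (adjusted p = 1.55e-05). Rgs1 (16.5-fold), Litaf (13.5-fold), the costimulatory receptor 4-1BB (Tnfrsf9, 9.79-fold), Fas ligand (Fasl, at least 2.86-fold), NKG2D (Klrk1, at least 4.82-fold), T-bet (at least 4.22-fold), interferon gamma (Ifng, at least 6.92-fold, adjusted p = 1.55e-05), Gzma (18.4-fold, adjusted p = 0.00182), Cd44 (8.41-fold, adjusted p = 3.66e-08), the survival gene Bcl2a1d (at least 4.83-fold) and Nrp1 (at least 13.2-fold, adjusted p = 2.42e-06) were also higher. Effector cytokines split into 2 higher and 3 lower of 6, with a median of -0.26, a mean of 0.47 and a downward fry test (adjusted p = 0.424).

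Of 17 naive and memory genes, 13 fell and none rose (0 and 15 adjusted over the list alone; median -2.26, fry adjusted p = 2.75e-05, adjusted p = 0.165 with an estimated correlation). The lymph node homing receptor Ccr7 was lower by 9.31-fold (adjusted p = 0.000434), the egress receptor S1pr1 by 8.49-fold (adjusted p = 6.18e-07), its regulator Klf2 by 8.46-fold (adjusted p = 2.15e-05), and Foxo1 by 4.79-fold. Itgae (at least 19.8-fold, adjusted p = 3.76e-06), the ubiquitin ligase Dtx1 (at least 9.09-fold, adjusted p = 2.23e-08), Socs3 (at least 8.19-fold), Txnip (12.2-fold) and Ccr9 (at least 6.21-fold) fell as well. Interferon-stimulated genes were lower in 7 of 18 cases and none was higher (0 and 10 adjusted over the list alone; median -0.58, fry adjusted p = 0.00178, adjusted p = 0.286 with an estimated correlation), such as Oasl2 (3.81-fold), Usp18 (4.39-fold) and Ifit3 (2.92-fold). T cell identity genes fell in 7 of 10 cases and rose in 1 (1 and 7 adjusted over the list alone; median -0.89, fry adjusted p = 8.82e-05, adjusted p = 0.190 with an estimated correlation). Lower members included the zeta chain Cd247 (2.65-fold, adjusted p = 0.000112) and the CD8 beta chain Cd8b1 (2.00-fold, adjusted p = 0.000660). B cell and myeloid markers gave no list call (medians 0.12 and 0.03, fry adjusted p = 0.935 and 0.971, myeloid mean -0.19), nor did the 2 hepatocyte markers tested (0.33, fry adjusted p = 0.524). The CD4 and regulatory T cell list of 2 markers was called through Nrp1 (fry adjusted p = 6.91e-05, 0.233 with an estimated correlation), as it was for late lesion against naive cells (0.000444 and 0.289).

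The day 12 array moved part of these values. Without it the difference was 5.60 for Xcl1, 3.12 for Gzma, -3.44 for Il7r and -2.33 for Ccr7, and without the day 8 array it was 5.57 for Gzma, all still called. The bound rose to at least 4.88-fold for Ctla4 without the day 12 array and to at least 6.28-fold for T-bet without the day 8 array. Median scaling gave 1230 calls and ended those of the glycolysis list (adjusted p = 0.187, range 1.55e-06 to 0.187) and the TCR regulator list (0.243, range 1.44e-06 to 0.243). Under it the median of all features was -0.20 here (-0.03 with quantile normalization), -0.17 (-0.04) for early lesion against effector cells and 0.15 (0.02) for late against early lesion cells. Differences in these comparisons are relative to that shift.

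Early lesion cells were compared with effector cells, which met the same epitope in an infection. S phase genes, most G2 and M phase genes, Xcl1, Ccl3, Lag3 and Tnfrsf9 were higher in the lesion cells, and most adhesion genes, Klrg1 and Zeb2 were lower. Xcl1 was 43.1-fold higher (10.93 ± 1.31 against 5.50 ± 0.13, adjusted p = 1.29e-05) and Kif15 at least 11.0-fold (adjusted p = 5.77e-06). Il7r was 22.9-fold lower (6.49 ± 1.14 against 11.01 ± 0.23, adjusted p = 1.22e-05) and Dtx1 at least 9.18-fold (adjusted p = 6.83e-08). There were 1956 calls, 874 higher and 1082 lower, of which 477 and 525 differed at least 2-fold.

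All 17 S phase genes were higher (17 and 0 adjusted over the list alone; median 1.87, fry adjusted p = 1.38e-05, adjusted p = 0.120 with an estimated correlation), as were 11 of 14 G2 and M phase genes (12 and 0 adjusted over the list alone; median 2.35, fry adjusted p = 0.000209, adjusted p = 0.168 with an estimated correlation). They included Rrm2 (6.99-fold, adjusted p = 1.45e-05), Uhrf1 (8.59-fold), Top2a (10.7-fold) and the checkpoint kinase Bub1b (4.92-fold, adjusted p = 3.70e-05), and the core histone gene H2bc3 rose 16.6-fold (adjusted p = 8.27e-06). Glycolysis enzymes Tpi1 (4.38-fold, adjusted p = 1.34e-05) and Gapdh (2.38-fold) were higher. So were Ccl3 (at least 8.07-fold, adjusted p = 7.95e-06), Ccl4 (4.68-fold), Tnfrsf9 (at least 8.87-fold, adjusted p = 1.71e-06), Spry2 (at least 6.04-fold), Ubash3b (4.24-fold), Litaf (4.96-fold), the phosphatase Dusp1 (3.81-fold), Ifng (3.38-fold) and Nrp1 (4.26-fold). Inhibitory receptors were higher in 3 and lower in 1 of 11 cases (3 and 1 adjusted over the list alone; median 0.71, fry adjusted p = 5.88e-05, adjusted p = 0.233 with an estimated correlation), with Lag3 at least 3.26-fold (adjusted p = 2.71e-06) higher. Of 9 transcription factors of chronic stimulation 3 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.43, fry adjusted p = 0.00178, adjusted p = 0.259 with an estimated correlation). Nr4a2 (10.2-fold, adjusted p = 4.14e-05) and Ikzf2 (at least 4.28-fold, adjusted p = 0.000183) rose.

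Cytotoxic and terminal effector genes were lower in 10 of 19 cases and higher in 1 (1 and 11 adjusted over the list alone; median -0.97, fry adjusted p = 0.00228, adjusted p = 0.285 with an estimated correlation). Klrg1 was lower by at least 3.60-fold (adjusted p = 5.25e-05), S1pr5 by 4.27-fold (adjusted p = 1.22e-05), Zeb2 by 3.45-fold and granzyme M (Gzmm) by at least 1.64-fold. Integrin and adhesion genes fell in 7 of 10 cases (0 and 8 adjusted over the list alone; median -1.01, fry adjusted p = 4.27e-06, adjusted p = 0.120 with an estimated correlation), including Itgb1 (3.45-fold, adjusted p = 3.31e-05) and the selectin ligand Selplg (2.32-fold). Cytokine receptor and signalling genes fell in 4 of 16 cases and none rose (0 and 4 adjusted over the list alone; median -0.56, fry adjusted p = 6.73e-05, adjusted p = 0.168 with an estimated correlation), with Il18rap 4.80-fold lower. Naive and memory genes were lower in 7 of 17 cases (1 and 8 adjusted over the list alone; median -0.95, fry adjusted p = 0.00503, adjusted p = 0.424 with an estimated correlation), among them Klf2 (7.29-fold) and S1pr1 (5.78-fold, adjusted p = 7.62e-06). Cxcr3 (5.97-fold), the stress genes Ier3 (5.91-fold) and Btg2 (3.89-fold), and the interferon-stimulated Usp18 (2.62-fold) and Ifit3 (2.38-fold) were lower. T cell identity genes fell in 7 of 10 cases and rose in 1 (1 and 7 adjusted over the list alone; median -0.84, fry adjusted p = 0.000243, adjusted p = 0.206 with an estimated correlation), Cd8b1 by 1.94-fold (adjusted p = 0.00126). B cell markers were lower in 7 of 9 cases (0 and 8 adjusted over the list alone; median -2.78, fry adjusted p = 0.00443, adjusted p = 0.285 with an estimated correlation). H2-Aa (13.7-fold, adjusted p = 0.000901) and Cd79a (at least 3.02-fold, adjusted p = 0.00357) were lower. Myeloid markers were lower in 3 of 8 cases (0 and 3 adjusted over the list alone; median -1.16, fry adjusted p = 0.000370, adjusted p = 0.274 with an estimated correlation), such as Cd163 (at least 2.74-fold) and Itgax (at least 8.11-fold, adjusted p = 7.31e-08).

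Without the day 12 array the difference was 6.20 for Xcl1 and -3.89 for Il7r, and without effector replicate 1 or 3 that of H2-Aa was -3.11 or -4.37. The bound of Cd79a was at least 1.52-fold without effector replicate 1 and at least 4.87-fold without replicate 3. Median scaling gave 863 calls, the fit of only these groups 1109 and the Cd79a and Cd79b covariate 308. That covariate ended the calls of Ccl4, Ikzf2, Dusp1, Ifng, Gapdh, Zeb2, Btg2, Ifit3, Nrp1, H2-Aa and Cd79a (adjusted p from 0.0503 to 0.790). Of 1661 calls that it ended here, 1056 kept at least 80% of their difference, 262 kept less than 50%, and the median standard error was 1.87 times as large. Zeb2 went from -1.79 ± 0.29 to -2.00 ± 0.56 and Gapdh from 1.25 ± 0.17 to 1.28 ± 0.33, whereas H2-Aa went from -3.78 ± 0.63 to -1.20 ± 0.84. Differences of genes outside the B cell and myeloid lists shrank as well, for Ifng from 1.76 ± 0.39 to 0.64 ± 0.65, for Nrp1 from 2.09 ± 0.39 to 0.56 ± 0.53 and for Ccl4 from 2.23 ± 0.30 to 1.19 ± 0.45. It also ended the list calls of inhibitory receptors (0.196, range 1.08e-05 to 0.196), chronic stimulation factors (0.150, range 8.15e-05 to 0.150), naive and memory genes (0.202, range 1.26e-05 to 0.202), myeloid markers (0.108, range 3.21e-05 to 0.108) and B cell markers (0.962, range 0.000415 to 0.962). Median scaling ended the list calls of cytotoxic genes (0.0581, range 6.72e-05 to 0.0581), T cell identity (0.0885, range 5.62e-05 to 0.0885) and inhibitory receptors (0.117), and the fit of only these groups those of naive and memory genes (0.0812) and B cell markers (0.0643).

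Effector and early lesion cells, each against the same naive arrays, shared 251 calls in the same direction (117 higher, 134 lower) and 13 in opposite directions. Independent lists of these sizes would share 30.9 higher and 28.6 lower. Across genes, which are not independent replicates, the differences of both comparisons correlated at 0.468, below the 0.518 that 100 simulated pairs of unchanged groups gave, with a covariance of 0.23 (simulated 0.0437). Early and late lesion cells against the same effector arrays shared 635 calls in the same direction (256 higher, 379 lower) and 9 in opposite directions. Independent lists would share 60.2 and 76.0, and the correlation was 0.622 (simulated 0.588) with a covariance of 0.334 (simulated 0.042). In the 100 simulated pairs, the number of shared calls had a median and a maximum of 0 for both overlaps. Unchanged groups give few calls that could be shared, so this cannot show what shared controls add to groups that do change. Groups of 3 control arrays cannot be split with 2 on each side, so part of the excess may come from the shared controls. The overlap of 251 was 119, 140 and 115 without naive replicates 1, 2 and 3, 146 without effector replicate 2, 130 with median scaling, 752 with array weights, 161 with the sex-linked covariate and 75 with the Cd79a and Cd79b covariate. The overlap of 635 was 403 without effector replicate 2, 407 without effector replicate 1 and late lesion replicate 1, 322 with median scaling, 419 with only the groups compared in each fit and 83 with the Cd79a and Cd79b covariate.

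Late and early lesion cells were compared to follow the cells over about 3 weeks of lesion growth. Late cells held less transcript of most S phase and G2 and M phase genes and more of most tissue residency and NK cell genes. E-cadherin (Cdh1) was 16.5-fold higher (10.94 ± 0.28 against 6.90 ± 0.43, adjusted p = 1.64e-06), the ATP-gated channel P2rx7 at least 6.16-fold (adjusted p = 5.20e-06) and the kinesin Kif5c 11.4-fold (adjusted p = 4.91e-06). The branched-chain aminotransferase Bcat1 was lower by at least 4.94-fold (adjusted p = 2.58e-05). Of 1735 calls, 907 were higher and 828 lower, with 398 and 359 at least 2-fold.

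Tissue residency genes rose in 7 of 10 cases and none fell (8 and 0 adjusted over the list alone; median 1.29, fry adjusted p = 5.11e-05, adjusted p = 0.120 with an estimated correlation). Beside P2rx7 they included the collagen-binding integrin Itga1 (5.95-fold, adjusted p = 0.00102), the liver homing receptor Cxcr6 (7.88-fold, adjusted p = 0.00737) and Rgs1 (3.03-fold, adjusted p = 0.000661). Cytotoxic genes rose in 9 of 19 cases and none fell (10 and 0 adjusted over the list alone; median 0.91, fry adjusted p = 0.00972, adjusted p = 0.289 with an estimated correlation). Fasl (2.76-fold), perforin (Prf1, 1.88-fold, adjusted p = 0.0120) and Klrd1 (3.68-fold, adjusted p = 0.00431) were higher. NK cell markers were higher in 3 of 4 cases (3 and 0 adjusted over the list alone; median 2.15, fry adjusted p = 0.00212, adjusted p = 0.190 with an estimated correlation), with Klrb1c 3.85-fold (adjusted p = 0.00306) higher. Probes of this receptor family can bind related transcripts. Blimp-1 (Prdm1, 4.62-fold, adjusted p = 0.00850, with overlapping ranges), Cxcr3 (2.87-fold), the SLAM family receptor Cd244a (5.43-fold, adjusted p = 0.00666), Cd7 (at least 3.61-fold, adjusted p = 1.06e-05), Myadm (7.13-fold), the survival gene Bcl2 (3.96-fold, adjusted p = 0.00117), Spry2 (3.11-fold), Btg2 (2.56-fold) and Klf6 (1.99-fold) were higher as well. The T cell identity list rose with 2 of 10 members called (2 and 0 adjusted over the list alone; median 0.37, fry adjusted p = 0.00197, adjusted p = 0.289 with an estimated correlation). Cd8a rose by 2.90-fold (adjusted p = 0.000443) and Cd3g by 2.01-fold (adjusted p = 0.00164).

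Of 17 S phase genes, 16 fell (0 and 17 adjusted over the list alone; median -1.08, fry adjusted p = 0.000176, adjusted p = 0.152 with an estimated correlation). Of 14 G2 and M phase genes, 10 fell (1 and 11 adjusted over the list alone; median -1.19, fry adjusted p = 0.0105, adjusted p = 0.285 with an estimated correlation). Examples are the replication factors Cdc45 (2.50-fold, adjusted p = 0.000547), Mcm7 (2.74-fold) and Cdc6 (2.65-fold), Rrm1 (2.05-fold) and Top2a (2.96-fold, adjusted p = 0.00252), and beside these lists Pclaf (3.93-fold) and the chromosomal passenger Cdca8 (4.16-fold, adjusted p = 0.000705) fell. Glycolysis genes fell in 6 of 12 cases and rose in 1 (1 and 7 adjusted over the list alone; median -0.56, fry adjusted p = 0.000711, adjusted p = 0.172 with an estimated correlation), with Pkm 2.01-fold, Ldha 2.04-fold and Tpi1 1.91-fold lower. Spermidine synthase (Srm, at least 2.95-fold, adjusted p = 0.000590), the proto-oncogene Myb (10.7-fold, adjusted p = 0.00252), the peptidase Dpp4 (5.50-fold), the chromatin organiser Satb1 (8.02-fold, adjusted p = 0.00516, with overlapping ranges), Oas3 (at least 1.72-fold) and the chaperone Hsp90aa1 (1.87-fold) were lower.

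Hepatocyte transcripts did not move together in the late group. Transferrin (Trf), 1 of 2 tested members of that list, rose at least 2.36-fold (adjusted p = 0.00153), in a list with median 1.23, fry adjusted p = 0.0242, adjusted p = 0.424 with an estimated correlation. On late lesion replicate 1 alone, Apoa1 stood at 8.38 (highest other array 5.26) and Alb at 7.71 (highest other array 5.17). The hepatocyte list call ended without the day 12 array (adjusted p = 0.0903), with cyclic loess (0.0508) and with only these groups fitted (0.108, range 0.000337 to 0.108).

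Without the day 12 array the difference was 4.08 for Cxcr6, 2.47 for Klrd1, -4.57 for Myb and -3.97 for Satb1. Without the day 8 array it was 1.93 for Cxcr6 and -2.82 for Myb. Without the day 12 array no early array detected Prdm1 or Cd244a, whose early mean was 5.51 in place of 6.51, and late cells were at least 4.42-fold and 7.09-fold higher. The count was 973 without the day 9 array, 1117 without late lesion replicate 3, 895 with only these groups fitted, 1125 with the median signal as a covariate and 617 with median scaling, which split them into 440 higher and 177 lower. Median scaling also ended the calls of Prf1, Klf6, Rrm1, Pkm, Ldha, Tpi1 and Hsp90aa1 (adjusted p from 0.0722 to 0.156) and cyclic loess that of Prf1 (0.0660, range 0.00325 to 0.0983). List calls that ended with median scaling were those of S phase (0.0581, range 2.43e-05 to 0.0581), G2 and M phase (0.163, range 0.00128 to 0.163), glycolysis (0.558, range 0.000183 to 0.558), cytotoxic (0.124, range 0.000175 to 0.124) and T cell identity genes (0.175, range 0.000458 to 0.175). The G2 and M phase list was not called with only these groups fitted (0.0736).

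**Figure D4:**
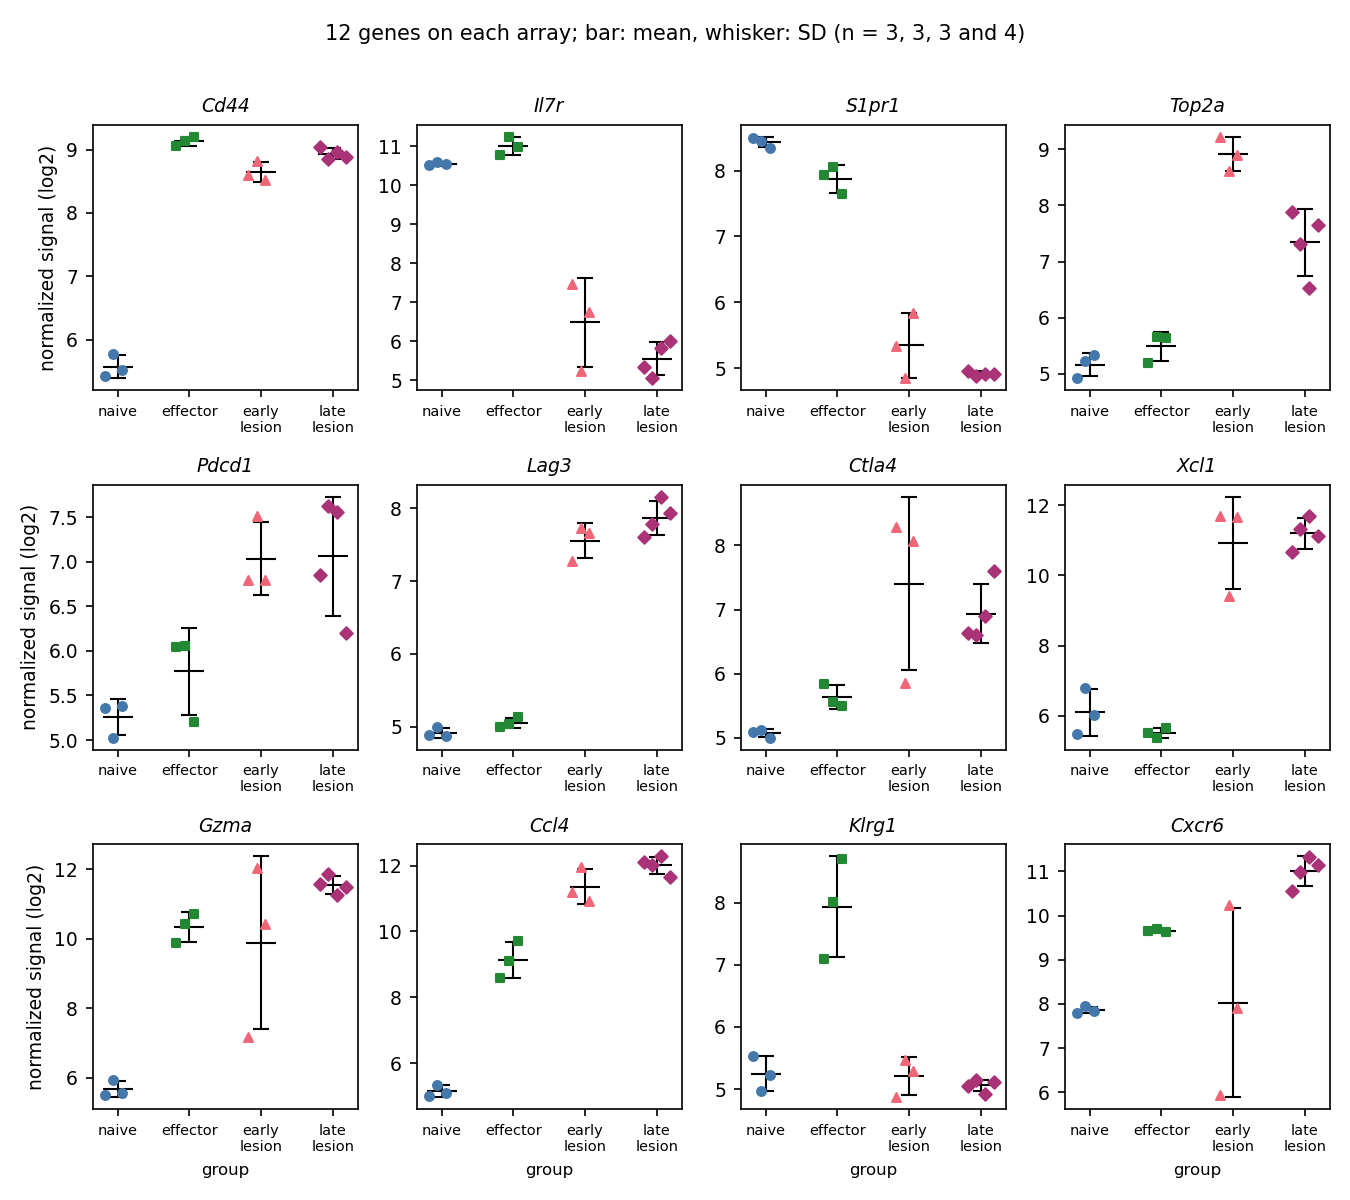
Each panel gives the normalized log2 signal of 1 gene on each of the 13 arrays by group (points), with the group mean as a bar and the SD as whiskers. Lag3 reaches 5.13 at most on naive and effector arrays and lies between 7.28 and 8.16 on lesion arrays, while Klrg1 lies between 7.09 and 8.70 on effector arrays and reaches 5.54 at most elsewhere.

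Late lesion cells against naive cells showed the change from the resting state after about a month of lesion growth. The adaptor Lat2 rose 64.2-fold (adjusted p = 1.88e-05), Gzma 58.2-fold (adjusted p = 8.49e-05), Rgs1 50.1-fold (adjusted p = 4.24e-09) and Ccl4 at least 69.7-fold (adjusted p = 4.24e-09). Satb1 was lower by 60.0-fold (adjusted p = 1.49e-05), Il7r by 31.9-fold (adjusted p = 1.44e-06) and Ccr7 by at least 20.5-fold (adjusted p = 6.19e-06). There were 2040 calls, 982 higher and 1058 lower, with 604 and 457 at least 2-fold. Naive and memory genes fell in 16 of 17 cases and rose in 1 (1 and 16 adjusted over the list alone; median -3.51, fry adjusted p = 4.27e-06, adjusted p = 0.120 with an estimated correlation), including S1pr1 (at least 5.94-fold) and Foxo1 (at least 4.60-fold).

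Tissue residency genes rose in 7 of 10 cases and fell in 2 (8 and 2 adjusted over the list alone; median 3.03, fry adjusted p = 3.48e-06, adjusted p = 0.120 with an estimated correlation). Litaf was 23.7-fold higher and Itgae lower by 21.5-fold (adjusted p = 1.22e-05). Chemokine genes rose in 6 of 11 cases and fell in 3 (6 and 3 adjusted over the list alone; median 3.06, fry adjusted p = 3.48e-06, adjusted p = 0.168 with an estimated correlation), Xcl1 by 34.5-fold (adjusted p = 6.19e-06). Inhibitory receptors were higher in 6 and lower in 2 of 11 cases (6 and 2 adjusted over the list alone; median 1.80, fry adjusted p = 3.30e-06, adjusted p = 0.120 with an estimated correlation). Lag3 (at least 3.97-fold, adjusted p = 5.95e-08), Cd244a (at least 8.38-fold) and Cd160 (5.18-fold) were higher. Factors of chronic stimulation rose in 5 of 9 cases and none fell (5 and 0 adjusted over the list alone; median 0.71, fry adjusted p = 5.25e-05, adjusted p = 0.120 with an estimated correlation). Nr4a2 (10.5-fold), Bhlhe40 (at least 7.26-fold) and Prdm1 (at least 5.23-fold) were higher. Cytotoxic genes rose in 12 and fell in 1 of 19 cases (14 and 1 adjusted over the list alone; median 1.13, fry adjusted p = 0.000243, adjusted p = 0.174 with an estimated correlation). Fasl (at least 7.89-fold), T-bet (at least 9.21-fold) and granzyme B (Gzmb, at least 3.43-fold, adjusted p = 0.00232) were higher. NK cell markers rose in 3 of 4 cases (3 and 0 adjusted over the list alone; median 3.09, fry adjusted p = 0.000243, adjusted p = 0.165 with an estimated correlation). Klra7 rose by at least 10.8-fold (adjusted p = 0.000257) and Klre1 by at least 7.06-fold (adjusted p = 0.000454). The CD200 receptor family gene Cd200r2 (at least 38.5-fold, adjusted p = 0.000115), Arap3 (39.2-fold) and Spry2 (at least 18.4-fold, adjusted p = 1.44e-08) were higher too.

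Part of the cell cycle lists was raised, with 9 of 14 G2 and M phase genes (10 and 0 adjusted over the list alone; median 1.19, fry adjusted p = 0.00376, adjusted p = 0.285 with an estimated correlation) and 8 of 17 S phase genes higher (10 and 1 adjusted over the list alone; median 0.64, fry adjusted p = 0.00291, adjusted p = 0.304 with an estimated correlation). Rrm2 was 7.49-fold and Top2a at least 2.75-fold higher. Interferon-stimulated genes were lower in 9 and higher in 1 of 18 cases (1 and 9 adjusted over the list alone; median -0.62, fry adjusted p = 0.000328, adjusted p = 0.233 with an estimated correlation). Oas3 (at least 4.97-fold, adjusted p = 5.33e-06) and Oasl2 (at least 3.95-fold) were lower. Socs3 (15.3-fold) and Tdrp (at least 25.6-fold, adjusted p = 1.74e-07) were lower, and Trf, a member of the hepatocyte list, was higher by at least 2.71-fold (adjusted p = 0.000235). The list of 2 tested hepatocyte markers was called (median 1.56, fry adjusted p = 0.00709, adjusted p = 0.334 with an estimated correlation). T cell identity genes fell in 4 and rose in 2 of 10 cases (2 and 5 adjusted over the list alone; median -0.51, fry adjusted p = 0.0132, adjusted p = 0.543 with an estimated correlation), a call that ended with median scaling (0.244) and in 2 other settings (range 0.00417 to 0.244). Median scaling gave 1118 calls and ended that of the S phase list (adjusted p = 0.187, range 0.000215 to 0.187).

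Late lesion cells differed from effector cells at 1111 features, 550 higher and 561 lower, with 373 and 308 at least 2-fold. Cd200r2 (at least 39.3-fold, adjusted p = 0.000291), Xcl1 (52.1-fold, adjusted p = 4.87e-06), Arap3 (at least 30.3-fold) and Spry2 (at least 18.8-fold) were higher. Satb1 (43.9-fold, adjusted p = 6.25e-05), Il7r (43.6-fold, adjusted p = 1.42e-06) and the zinc finger factor Klf3 (at least 12.4-fold, adjusted p = 7.04e-06) were lower. Tissue residency genes were higher in 6 of 10 cases and none was lower (6 and 0 adjusted over the list alone; median 2.55, fry adjusted p = 1.01e-05, adjusted p = 0.120 with an estimated correlation). P2rx7 was higher by at least 7.23-fold, Litaf by 8.75-fold and Rgs1 by 6.68-fold. Inhibitory receptors were higher in 4 and lower in 2 of 11 cases (6 and 2 adjusted over the list alone; median 1.01, fry adjusted p = 2.07e-05, adjusted p = 0.168 with an estimated correlation). Lag3 (at least 4.05-fold, adjusted p = 4.89e-07) and Cd244a (at least 8.57-fold) were higher. Factors of chronic stimulation rose in 4 and fell in 1 of 9 cases (4 and 1 adjusted over the list alone; median 1.22, fry adjusted p = 0.000275, adjusted p = 0.152 with an estimated correlation). Nr4a2 was 11.5-fold higher and Eomes lower by 6.21-fold (adjusted p = 0.00689). NK cell markers were higher in 3 of 4 cases (3 and 0 adjusted over the list alone; median 2.53, fry adjusted p = 0.000444, adjusted p = 0.122 with an estimated correlation), Klra7 by at least 11.1-fold (adjusted p = 0.000535). Ccl3 (at least 12.1-fold, adjusted p = 1.25e-06), Ccl4 (7.32-fold), Tnfrsf9 (at least 7.34-fold), Nfil3 (14.1-fold), the secreted protein Fgl2 (17.0-fold), Cd7 (at least 4.24-fold) and Bcl2 (5.25-fold) were also higher.

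Naive and memory genes were lower than in effector cells in 11 of 17 cases and higher in 1 (1 and 11 adjusted over the list alone; median -1.35, fry adjusted p = 0.000209, adjusted p = 0.172 with an estimated correlation). Klf2 (at least 7.61-fold, adjusted p = 4.87e-06) and S1pr1 (at least 4.05-fold) were lower. Integrin and adhesion genes fell in 4 and rose in 1 of 10 cases (1 and 4 adjusted over the list alone; median -0.34, fry adjusted p = 3.16e-05, adjusted p = 0.120 with an estimated correlation), Itgb1 by 2.64-fold (adjusted p = 0.000188). Klrg1 (at least 4.21-fold, adjusted p = 2.78e-05), Il18rap (at least 7.65-fold) and Oas3 (at least 4.72-fold) were lower. B cell markers were lower in 7 of 9 cases (0 and 7 adjusted over the list alone; median -2.68, fry adjusted p = 0.00929, adjusted p = 0.259 with an estimated correlation), such as Cd79b (10.2-fold, adjusted p = 0.000417). Myeloid markers were lower in 3 of 8 cases (0 and 3 adjusted over the list alone; median -0.35, fry adjusted p = 0.00112, adjusted p = 0.344 with an estimated correlation), such as Cd163 (at least 3.21-fold) and Itgax (at least 9.49-fold, adjusted p = 3.56e-08).

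The count was 747 without effector replicate 2, 684 without effector replicate 1 and late lesion replicate 1, 630 with median scaling and 137 with the Cd79a and Cd79b covariate. The covariate ended the calls of Cd200r2, Arap3, Fgl2, Ccl4, Cd244a, Bcl2, Klra7, Satb1, Eomes, Cd79b and Cd163 (adjusted p from 0.0501 to 0.647) and of the B cell (0.416, range 0.000820 to 0.416) and myeloid lists (0.170, range 9.16e-05 to 0.170). Of 985 calls that it ended here, 674 kept at least 80% of their difference, 131 kept less than 50%, and the median standard error was 2.04 times as large. Bcl2 went from 2.39 ± 0.31 to 2.72 ± 0.62 and Satb1 from -5.46 ± 0.62 to -5.05 ± 1.28, whereas Cd79b went from -3.35 ± 0.49 to -0.51 ± 0.39, Cd163 from -2.65 ± 0.25 to -1.56 ± 0.39 and Ccl4 from 2.87 ± 0.28 to 1.78 ± 0.46. Without effector replicate 1 or 3 the difference of Cd79b was -2.65 or -3.98. The myeloid list was not called without effector replicate 2 or 3 (adjusted p = 0.0712 and 0.0604), the integrin list with median scaling (0.0853, range 3.23e-06 to 0.0853), or the B cell list with only these groups fitted (0.0674).

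Some T cell genes had been set to be named whatever their result. Lag3 averaged 4.92 ± 0.07 in naive, 5.05 ± 0.07 in effector, 7.56 ± 0.24 in early lesion and 7.87 ± 0.23 in late lesion cells, higher in each lesion group against each spleen group. Pdcd1 averaged 5.26 ± 0.20, 5.77 ± 0.49, 7.04 ± 0.41 and 7.06 ± 0.67 in the same order, higher in both lesion groups against naive and against effector cells. The early call of Pdcd1 against effector cells ended without effector replicate 3 (adjusted p = 0.0836), without the day 12 array (0.0678) and in 3 other settings (range 0.00908 to 0.165). Its late call ended without effector replicate 3 (0.107), without late lesion replicate 2 (0.0610) or 3 (0.0581) and in 3 other settings (range 0.00399 to 0.226). Ctla4 averaged 5.07 ± 0.06, 5.63 ± 0.19, 7.40 ± 1.35 and 6.94 ± 0.46, higher in both lesion groups against naive cells (late at least 2.07-fold, adjusted p = 0.00810) and in early lesions against effector cells (at least 2.93-fold, adjusted p = 0.0173). The latter call ended without effector replicate 2 (0.0531), the day 8 array (0.0686) or the day 9 array (0.0719) and in 3 other settings (range 4.58e-05 to 0.230), and the bound was at least 4.99-fold without the day 12 array.

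Havcr2, which encodes TIM-3, was called in early lesions against naive cells (at least 2.67-fold, adjusted p = 0.0378). That call ended in 10 of 28 alternatives (range 0.0136 to 0.119). Without the day 12 array the early mean was 6.30 in place of 7.30 and the bound at least 1.35-fold (adjusted p = 0.0935). It also ended when any 1 naive replicate was left out (0.0792, 0.112 and 0.0649), which leave the early arrays in place. Gzmb was higher in early lesion than in naive cells (at least 1.60-fold, adjusted p = 0.0480), and at least 2.80-fold without the day 8 array. Without the day 12 array the early mean was 5.61 in place of 6.57, below the detection floor of the naive arrays, so no bound remained (adjusted p = 0.136). Its call ended in 19 of 28 alternatives (range 0.00246 to 0.155), including each that left out 1 array except the day 8 array. In late lesions Gzmb was higher than in effector cells (4.70-fold, adjusted p = 0.0170), a call that ended without effector replicate 1 or 2 (0.0674 and 0.0641) and in 3 other settings (range 0.000245 to 0.609). Prf1 averaged 11.41 ± 0.24, 11.78 ± 0.45, 11.29 ± 0.13 and 12.20 ± 0.26 from naive to late lesion cells and was higher in late lesion than in naive cells (1.73-fold, adjusted p = 0.0177). That call ended without naive replicate 1 (0.0922) or late lesion replicate 3 (0.0509) and with median scaling (range 0.00408 to 0.382). Another probe of Prf1 had the opposite sign in early lesions against naive cells and in late lesions against effector and early lesion cells.

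Ifng averaged 4.97 ± 0.06, 6.92 ± 0.66, 8.68 ± 0.74 and 7.86 ± 0.52 in the same order, higher in each of the 3 other groups than in naive cells, although the effector call ended in 2 settings (range 0.000288 to 0.0578). Tbx21 averaged 9.35 ± 0.55 in effector and 7.96 ± 1.13 in early lesion cells (2.61-fold lower, adjusted p = 0.0361, with overlapping ranges). This call ended without effector replicate 2 (0.0920) or 3 (0.127), without the day 8 (0.135) or day 9 array (0.0830) and in 3 other settings (range 0.00196 to 0.145). Eomes was higher in effector than in naive cells (5.38-fold, adjusted p = 0.0342), a call that ended when any naive or effector array or late lesion replicate 3 was left out (0.0509 to 0.128) and in 2 other settings (range 0.000527 to 0.414). Cd44 averaged 9.13 ± 0.07 in effector, 8.65 ± 0.16 in early and 8.93 ± 0.09 in late lesion cells. Its lower level in early lesion than in effector cells (1.40-fold, adjusted p = 0.0418) was not called in 17 of 29 alternatives (range 0.00652 to 0.313), including each that left out an effector array, naive replicate 1 or 3, the day 8 or day 9 array or late lesion replicate 2 or 3. Tnf and Alb failed the detection filter, and Tox, Tcf7 and Mki67 were not analysed here.

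**Figure D5:**
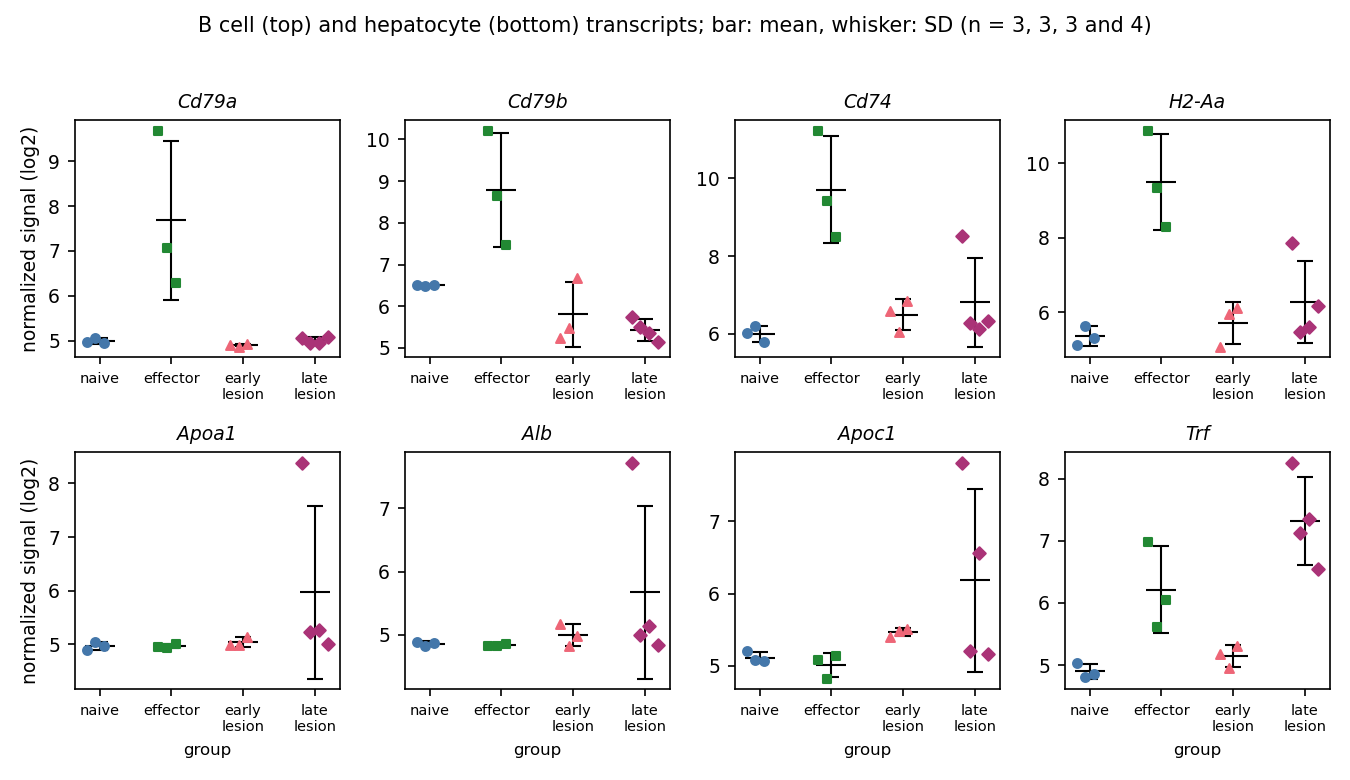
Points give the normalized log2 signal of 4 B cell or MHC class II transcripts (top) and 4 hepatocyte transcripts (bottom) on each array by group, with mean (bar) and SD (whiskers). Cd79a and Cd79b stand highest on effector replicate 1, and Apoa1, Alb, Apoc1 and Trf on late lesion replicate 1.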

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

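Tests of the B cell, myeloid and hepatocyte explanations and of the day 12 array, and the use of Cd79a and Cd79b as a covariate, were chosen only after the result was seen, whereas the test of dim probes was set before. Late lesion, the largest group, was the only one in which a single outlying array was looked for. Of 128 quantities looked at there, 8 had 1 array whose gap to its nearest neighbour took up more of the group's range than Dixon's 95% limit. Chance alone gives about 1 in 20, here 6.4, and late lesion replicate 1 was the outlying array in 6 of the 8.

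On late lesion replicate 1, the gap was 0.947 of the range for Ccr9 (5.17, next array 4.98), 0.914 for Cd74 (8.52, next 6.33), 0.894 for Klf2 (5.26, next 4.93) and 0.874 for Myb (5.76, next 5.17), each highest there. Cd8b1 was lowest there (10.97, next 11.35, gap 0.866). Ccl5 was lowest there too (12.55, gap 1 of the range), because the other arrays tie at 13.01, a value set by quantile normalization at the top of the scale. Itgae was highest on late lesion replicate 4 (7.73, next 5.51, gap 0.88), and Nfil3 on replicate 3 (9.66, next 9.48, gap 0.854).

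Counting members of the hepatocyte list whether tested or not, 14 were detected on late lesion replicate 1, against 2 on a naive array and 4 on any of the other arrays.

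B cell transcripts stood out in the effector arrays. All 9 tested members of the B cell list ranked the arrays in 1 order of the 6 possible, effector replicate 1 highest, 2 next and 3 lowest, with Cd74 at 11.22, 9.41 and 8.50 and Cd79b at 10.20, 8.65 and 7.48. This is consistent with RNA from B cells in those samples, although the sort for CD8 and Thy1.1 would be meant to remove them. Members with 1 source do not rank the arrays independently, and Ebf1 and the Fcer2a probe used were detected on all 13 arrays. The B cell and myeloid lists share 0 genes. Of 8 myeloid markers, 2 gave that order while 7 were highest on the same replicate 1. Those giving it, Marco and Siglech, were detected on all 13 arrays, and Itgax ranked the effector arrays in reverse. The other markers differed from the B cell order only in replicates 2 and 3. This count therefore cannot decide whether myeloid or dendritic cells gave part or all of the class II transcripts. With the Cd79a and Cd79b covariate, 115 genes in place of 444 were called between effector and naive cells, but that covariate also differs between these groups. Of 339 calls that ended, 220 kept at least 80% of their difference, such as Gzma (4.66 ± 0.81 to 4.97 ± 1.40), and lost precision, and 52 kept less than 50%, such as Cd74 (3.71 ± 0.65 to 1.36 ± 0.75). Class II and B cell genes expressed by the T cells themselves were not tested.

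Hepatocyte transcripts stood out on late lesion replicate 1. Of 19 hepatocyte markers with a probe, 15 had their highest value of all arrays there, with Apoa1 at 8.38 and Alb at 7.71, consistent with RNA from hepatocytes in that liver sample that the sort would be meant to remove. A general rise of dim probes would raise other markers alike. Only 5 of 24 erythroid, platelet, endothelial and stellate markers were highest there, and 1.87% of 13007 probes undetected on all other arrays were detected on it, which argues against that explanation. Among the late arrays, this array was also highest for S100a8 (8.46, next 5.78), Lyz2 (9.76, next 7.25) and H2-Ab1 (9.13, next 7.12), but not for Cd163, which no late array detected. Clec4g, an endothelial marker, and Ppbp, a platelet marker, were detected on this array alone. These values bear on a wider mix of liver cells, which was not tested, nor was a biological difference of that day 32 sample. Leaving this array out with effector replicate 1 gave 1679 calls between late and early lesions in place of 1735.

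The day 12 array lay nearer to the late arrays than the other early arrays did, with a mean correlation of 0.919 against 0.824 for day 8. The low signal of the day 8 array may add to that gap, but the day 9 array, which is not dim, had 0.864, nearer to day 8 than to day 12. For 2074 genes called between the late arrays and the other 2 early arrays, the day 12 array stood at a median position of 0.496 from the early (0) to the late level (1), with 88.7% of genes on the late side of the early mean. The same measure gave -0.003 for day 8 (1220 genes) and -0.00475 for day 9 (975 genes). For these, the early level included the day 12 array itself and the called genes were other sets. The positions are therefore not on 1 scale. The later day of sampling could account for this, but with 1 array per day, day and sample cannot be told apart.

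Other splits of the arrays were run for each count of calls, with 1 split, the real one, giving as many calls in every comparison. For the 3 comparisons of 3 with 3 arrays, the 10 splits are too few for a share under 0.05. The real counts were 444, 2197 and 1956, and the highest others 0, 0 and 3. With 35 splits of 3 and 4 arrays, the real split alone gave a share of 0.0286, under 0.05 for each comparison taken singly. These comparisons share arrays and their number was not corrected for, so chance is made less likely but is not excluded. Late against early lesions gave 1735 with 541 as the highest other, in a split that placed late lesion replicate 1 with early arrays. Late lesions against naive cells gave 2040 with 224 as the highest other, and against effector cells 1111 with 99.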

How the results depend on the processing

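The 3 covariates and the setting without effector replicate 1 and late lesion replicate 1 were chosen only after the result was seen. Outside the settings that leave out 1 array, 105 of 134 counts stayed within 1.5 times and 29 moved. Of 9698 values of named genes, 9180 kept their direction and side of the threshold, 441 lost and 75 gained a call and 2 reversed. Of 2526 list values 2243 kept them, 222 lost and 57 gained a call, and in 4 the direction of the test turned. The cause of the changes was not tested, except that a 2-fold threshold calls fewer features by construction. Dim probes limit what can be seen, since a fold near background is a lower bound.

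In the order effector and early lesion against naive, early lesion against effector, late against early lesion, late lesion against naive and against effector, median scaling gave 256, 1230, 863, 617, 1118 and 630 calls, and the overlaps 130 and 322. A 2-fold threshold left 1155, 1002, 757, 1061 and 681 in the last 5. Fits of only the groups compared gave 1109 for early lesion against effector and 895 for late against early lesion, with 419 in the second overlap. Array weights gave 1698 for effector against naive, with 752 in the first overlap. The Xist and Eif2s3y covariate gave 263 there and an overlap of 161, and the Cd79a and Cd79b covariate 115, with 308 and 137 for early and late lesion against effector and overlaps of 75 and 83. The median signal covariate gave 1125 for late against early lesion. Without effector replicate 1 and late lesion replicate 1 the counts were 282 for effector against naive, 684 for late lesion against effector and 407 in the second overlap.

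Leaving out each array in turn gave 203 to 584 calls for effector against naive, 1534 to 2296 and 1349 to 2026 for early lesion against naive and effector, 973 to 2063 for late against early lesion, 1448 to 2304 and 747 to 1278 for late lesion against naive and effector, and overlaps of 115 to 287 and 403 to 711. Of 104 such counts, 92 stayed within 1.5 times. Of 7839 named gene values 353 lost and 32 gained a call, of 1950 list values 50 and 41, and none reversed.

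The direction of the test turned, while the median kept its sign, for integrins in early lesion against naive with median scaling (-0.43), residency genes there with only those groups (0.26, fry downward, adjusted p = 0.0808) and costimulation in late lesion against effector with camera (-0.60). The median of B cell markers in late lesion against effector reversed with the Cd79a and Cd79b covariate (0.45). With it the median alone also turned sign, while the test kept its direction and its call ended, for B cell markers (0.26, from -2.78), myeloid markers (0.32, from -1.16), TCR regulators (-0.09, from 0.19) and residency genes (0.15, from -0.01) in early lesion against effector and for myeloid markers in late lesion against effector (0.54, from -0.35). With that covariate, which holds the gene itself, Cd79a reversed for early (0.26) and late lesion (0.51) against effector.

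Replicate numbers did not pair samples, since deviations of same-numbered arrays correlated at -0.227 to 0.218. Other pairs gave -0.271 to 0.329, highest for naive replicate 2 with day 9. With a replicate block, 388, 2146, 1867, 1299, 1938 and 959 features were called and the overlaps were 226 and 553. The files show no slide, so a shared batch was not tested.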

Other observations

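These genes were chosen after their values were seen. Liver lesion cells at both stages shared changes against both spleen groups. In all 4 of those comparisons, 197 features were called higher and 223 lower. The comparisons share arrays, and tissue and antigen setting differ together. Beside Xcl1, Lag3 and Il7r, the smallest of the 4 fitted differences was 3.06 for Nfil3, a leucine zipper factor (largest adjusted p = 4.94e-05). Genes lower in each comparison included the glycosyltransferase Galnt10, with a smallest fold of 12.1 (largest adjusted p = 0.00144), the adaptor Nck2 (4.92-fold, 0.00690) and the beta-catenin cofactor Bcl9l (4.87-fold, 0.00261).

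Some genes moved in opposite directions in effector and early lesion cells, each against naive cells. The transferrin receptor Tfrc was lower in effector cells (-1.48, adjusted p = 0.0471) and higher in early lesion cells (1.22, adjusted p = 0.0358), and so were the replication fork gene Timeless (-1.35 and 0.92, adjusted p = 0.0177 and 0.0358) and the nuclear lamin Lmnb2 (-0.72 and 0.66, adjusted p = 0.0135 and 0.00618). The nuclear receptor Rora (1.79 and -0.91, adjusted p = 0.00309 and 0.0423) and the innate sensor Nod1 (1.52 and -0.70, adjusted p = 9.08e-05 and 0.00878) were higher in effector and lower in early lesion cells. Against effector cells, Cdh1 was lower in early (-1.09) and higher in late lesion cells (2.95), as were Cd8a (-0.69 and 0.84) and Actn2 (-1.21 and 1.51), while the arginine methyltransferase Prmt1 was higher early (0.84) and lower late (-0.84).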
